A study of Mus musculus with 6 samples.

How the data were processed

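RNA was profiled in 6 libraries of NIH3T3 mouse fibroblasts, 3 from wild type cells and 3 from cells overexpressing the circular RNA F-CircAE. Per the labels' protocols, RNA was treated with DNase I, libraries were made with the NEBNext Ultra RNA kit, and paired-end reads of 125 or 150 bp were generated on an Illumina HiSeq instrument. Groups came from the genotype and title given for each sample, and replicate numbers from the title. Per the submitters' processing notes the genome build was mm10; the aligner, the counting program, its use of strand and the annotation version are not given in the sources used here. Each deposited file holds FPKM values for Ensembl gene IDs, per the file headers, that is reads scaled to gene length and library size by the authors.

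Gene symbols, coordinates and gene lengths were taken from the GENCODE M21 annotation of the mm10 assembly and a table of gene names. Of 24938 IDs 24816 had a symbol and 122 did not. Overlaps with neighbouring genes were read from the same annotation. Among the named genes, exons of Cdc20, Cox4i1, Atp5o, Dusp1, Ei24, Fn1, Mmp11, Pes1, Rps25, Gm15792 and Runx1 overlap those of a gene on the other strand, so part of their reads is uncertain where strand was not used. A further annotated copy of Atp5o overlaps it on the same strand.

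The FPKM values of low genes were whole multiples of a step, from which the relative scale of each library and the reads of each gene were recovered. The length used was the annotated exon union where it gave whole reads in all 6 libraries within 0.01 reads plus a relative 1e-08 (19832 genes, 79.5%), and otherwise the smallest length that did (5106 genes). Since that length was searched for, whole reads at those 5106 genes are no independent check. On simulated data the procedure returned every read count of 99.5% of genes exactly. The simulation took the lengths found above as true, so a searched length that is too short would not show as an error in it. The library scales differed by at most 0.0066% from median-of-ratios size factors of the recovered reads, so the deposited FPKM values appear to be scaled by such factors rather than by total reads; this was read from the values and no source states it. Total reads divided by the scale lay between 0.976 and 1.02. Recovered reads were used for depth, for the comparison of library pairs and for added alternatives, and not for the main test. They cover counting error only, since reads from amplified libraries are not independent molecules.

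The planned main test assumed counts. Because the deposited values are FPKM, the test written beforehand for normalized values was used in its place, namely limma 3.58.1 in R 4.3.3 with trend and robust moderation on log2(FPKM + 1), with group as the only term. The rule set beforehand gave a pseudocount of 1, or 0.1 for files with small sums, and 1 was used since FPKM sums per library (353510 to 380910) were judged large enough for it. Genes with FPKM above 1 in at least 3 libraries were tested (12222), leaving 12716 untested. Calls were made at a Benjamini-Hochberg adjusted p of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. The test was run on simulated data with 200 genes changed by known folds of FPKM + 1. Noise was independent between genes and libraries, and a gene had the same spread in every library. There were 9 false calls at 2-fold, 9 at 1.5-fold and 0 at 0.32 on the log2 scale.

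The 34 gene lists were written before the data were examined. They were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the 33 lists with a tested member. Camera compares a list with the other genes. Fry tests whether a list's genes move, on balance, one way and does not compare them with other genes. List means per library were compared with an exact two-sided permutation test. Pairs of libraries were compared by the chi-square per gene over genes of at least 20 reads in the pair, with 1000 bootstrap draws over genes.

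The rule for named genes was set before the data were examined. It took Runx1 and Runx1t1, then genes past the threshold, of which there were none, and with fewer than 10 such genes the 10 with the smallest p. A further rule was added after the values were seen and took the 2 members with the smallest p of each of the 13 lists past camera; a gene that it took is not reported here. Fn1, Clec3b, Ccl9 and Errfi1 were also chosen after their values were seen.

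Alternatives planned beforehand were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, the replicate number as a block, leaving out each library, a correction for GC content with and without the block, a test against a 1.5-fold change, and the 2 other list tests. Added after seeing the data were limma-voom on recovered reads, the same with sample quality weights, array weights, averaging control replicates 1 and 2 with and without array weights, rescaling to total reads and to the upper quartile, quantile normalization, protein-coding genes only, and removal of a gene length trend. GC content was available for 99.8% of tested genes and length for 100%. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.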

Results

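Gene expression was measured by RNA sequencing in NIH3T3 cells, an established mouse embryonic fibroblast line. The 3 control libraries came from wild type cells and the 3 other libraries from cells overexpressing F-CircAE, a circular RNA related to AML1-ETO. AML1-ETO is the fusion of the transcription factor gene RUNX1 with RUNX1T1 in human acute myeloid leukaemia, and a circular RNA is a transcript whose ends are joined. The design implies a single comparison, which asks how the transcriptome of the overexpressing cells differs from that of wild type cells. The controls are labelled wild type, and no group with an empty vector is included. Effects of the overexpression procedure therefore cannot be told apart from those of the circular RNA. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Each library lists 24938 genes in FPKM. The reads behind these values, recovered as described under the processing, numbered 19976826, 20936522 and 19001957 in control replicates 1, 2 and 3, and 16969814, 21843803 and 18696507 in overexpression replicates 1, 2 and 3.

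The libraries did not separate by group on the leading principal component, which held 35.5% of the variance. Control replicates 1 and 2 lay at -13.9 and -13.3 on it, whereas control replicate 3 lay at 11.2 and overexpression replicate 1 at 16.6. Control replicates 1 and 2 were close to counting noise. The chi-square per gene between them was 1.46 (95% bootstrap interval 1.41 to 1.52, where counting error alone gives 1), and 40 of 14529 genes (0.28%) differed. In the other 14 pairs of libraries the chi-square per gene ran from 5.15 to 25.1 and 15.0% to 40.7% of genes differed. Because a difference beyond counting error remained, both libraries were entered separately and n = 3 in each group, except in the alternatives that average or leave out libraries. The chi-square does not show that they came from separate cultures, and they differed far less than any other pair. A difference beyond counting error is thus no proof of independent replicates. If they share an RNA or a culture, control SDs, standard errors and intervals at n = 3 may be too small.

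**Figure D1:**
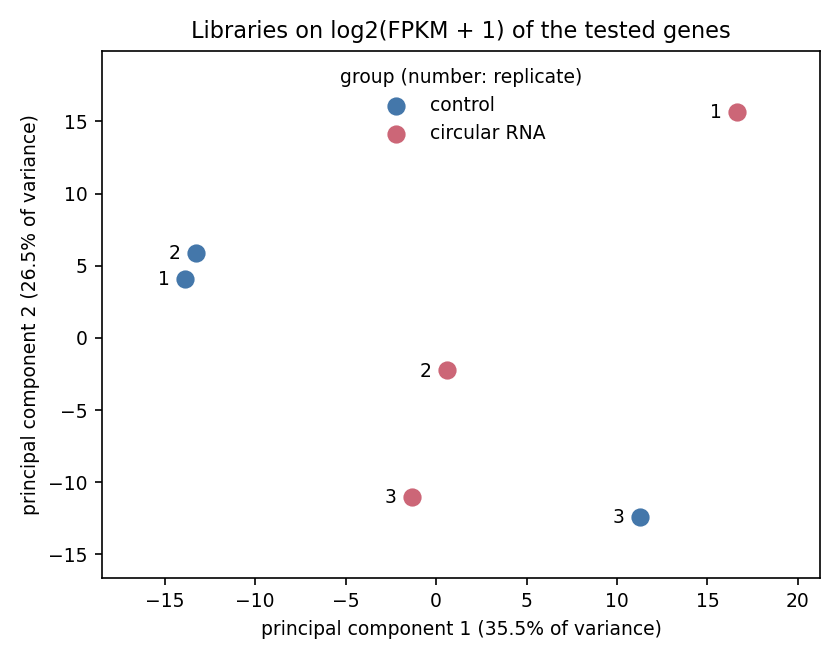
Position of the 6 libraries on principal components 1 (35.5% of variance) and 2 (26.5%) of log2(FPKM + 1) over the tested genes, in arbitrary units. Each point is a library, coloured by group and numbered by replicate; control replicates 1 and 2 lie together at the left, at -13.9 and -13.3, and control replicate 3 lies at 11.2.

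No gene differed between circular RNA overexpression and control at an adjusted p below 0.05. Among 12222 tested genes the smallest adjusted p was 0.260 (limma, Benjamini-Hochberg). At an unadjusted p below 0.05 there were 632 genes, 350 higher and 282 lower with overexpression, where chance alone gives 611 for independent libraries. This split depended on the scaling, with 174 higher and 453 lower after rescaling to total reads and 217 higher and 384 lower after rescaling to the upper quartile. Limma-voom on the recovered reads, which tested 14473 genes, also gave 0 genes, with 755 at an unadjusted p below 0.05. Averaging control replicates 1 and 2 to 1 library gave 0 genes and 240 at an unadjusted p below 0.05. The groups did not overlap in 1405 genes (11.5%), against 10% by chance if all 6 libraries are independent. The near-identical control replicates 1 and 2 put that in doubt. If they act as 1 library, the share by chance is higher than 10%. The median absolute log2 fold change was 0.08 and the median standard error 0.09. On the log2(FPKM + 1) scale, the 95% interval excluded a 2-fold change either way for 96.6% of tested genes. It excluded a 1.5-fold change for 89.1%. These shares concern folds of FPKM + 1 and do not bound the FPKM ratios of low genes. Hist1h3h, for example, counts among the 96.6% with an interval of -0.96 to -0.09, while its mean FPKM differed 2.01-fold. Data were simulated for this comparison over 12222 genes with independent noise, with folds again of FPKM + 1. The same test recovered 87% of 200 genes changed 2-fold, 59.5% of 200 changed 1.5-fold and 0% of 200 changed by 0.32 in log2. The simulated libraries were independent and equally noisy. They held neither a near-identical control pair nor the unequal spread of the real libraries, so the recovered shares need not hold for the real comparison.

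The count of 0 genes changed with 2 single libraries and with library weights. Without control replicate 3, Ccl9, which encodes a chemokine, and Errfi1, which encodes a feedback inhibitor of EGF receptor signalling, passed with log2 fold changes of -0.997 (limma adjusted p = 0.018) and -0.96 (limma adjusted p = 0.045). Control replicate 3 held 34.7 FPKM of Ccl9, beside 67.9 and 68.3 in control replicates 1 and 2 and 32.9, 33.8 and 34.1 in the overexpression libraries. Errfi1 stood at 34.7 FPKM in control replicate 3, at 86.4 and 89.4 in the other controls, and at 47.6, 43.6 and 43.2 with overexpression. Without overexpression replicate 1, the microRNA gene Mir7061 passed with a log2 fold change of -1.55 (limma adjusted p = 0.042). It rests on 6, 6 and 5 reads in the controls and 1 and 1 in overexpression replicates 2 and 3. Ccl9 and Errfi1 were named after their values were seen, whereas Mir7061 is among the 10 genes with the smallest p. Weighting the libraries by their estimated quality was tried only after the count of 0 was known. It gave 729 of 14473 tested genes in limma-voom on the recovered reads. Array weights on log2(FPKM + 1) gave 2241 of 12222 tested genes. With control replicates 1 and 2 averaged to 1 library, array weights gave 0 genes (smallest limma adjusted p = 0.441, 481 at an unadjusted p below 0.05).

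The mouse parent genes of the fusion were at similar levels in both groups. Runx1 (ENSMUSG00000022952, chromosome 16, 92601466 to 92826149, mm10) had 5.29 ± 0.72 FPKM in control and 5.25 ± 0.42 with overexpression (SD, n = 3). Its log2 fold change was -0.004 with a 95% interval of -0.25 to 0.24 and an adjusted p of 0.998 (limma). Runx1t1 (ENSMUSG00000006586, chromosome 4, 13743436 to 13893649) had 1.67 ± 0.21 FPKM in control and 1.66 ± 0.21 with overexpression (SD, n = 3). Its log2 fold change was -0.006, with a 95% interval of -0.26 to 0.25 and an adjusted p of 0.996 (limma). The fusion is of human genes and the files list mouse genes, so these values bear on the overexpression only as far as its reads map to the mouse genes. The sign of both near-zero values depended on the setting. The circular RNA itself was not analysed here.

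Pdk4 had the smallest p among protein-coding genes. It encodes a kinase that inhibits the pyruvate dehydrogenase complex, and lies on chromosome 6 from 5483351 to 5496309 (ENSMUSG00000019577). Control libraries held 44.4, 46.0 and 42.8 FPKM and overexpression libraries 24.8, 31.5 and 28.4 FPKM. The means were 44.4 ± 1.6 and 28.3 ± 3.32 FPKM (SD, n = 3), a ratio of 1.57 of control to overexpression. The log2 fold change was -0.64 with a standard error of 0.09, and the difference did not pass after adjustment (limma adjusted p = 0.493). Ces1g, a carboxylesterase gene of a family of close paralogs on chromosome 8 (93302369 to 93337308), had 7.23 ± 0.46 FPKM in control and 4.30 ± 0.68 with overexpression (SD, n = 3; limma adjusted p = 0.510). All 3 control libraries lay above all 3 overexpression libraries for both genes. Genes picked for a small p tend to separate in this way. The groups did not overlap in 1405 tested genes (11.5%, against 10% by chance for independent libraries). With array weights both passed, at limma adjusted p = 0.017 each, and with quality weights Pdk4 passed at 0.0023 and Ces1g at 0.012, but neither passed with array weights once control replicates 1 and 2 were averaged.

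The 8 other genes among the 10 with the smallest p were 6 small RNA genes, an antisense gene and a processed pseudogene, none of which passed. Gm25014, a small nuclear RNA gene on chromosome 8 (13283115 to 13283217), overlaps Dcun1d2 on the same strand. It had 0 reads in each control library and 3, 3 and 4 reads with overexpression. Gm26202, a small nucleolar RNA gene on chromosome 18 (75001880 to 75001944) within Rpl17, had 3 reads summed over the controls and 17 over the overexpression libraries. Gm24888, a small nucleolar RNA gene on chromosome 7 (109521280 to 109521409) within Rpl27a, had 1 and 14 reads. Lower in the overexpression libraries was Mir7061 on chromosome 7 (130908268 to 130908335), with 17 and 4 reads, which overlaps Plekha1 on the same strand. Also lower were Gm22661 on chromosome 13 (95332618 to 95332749), with 41 and 15 reads, and Gm22965 on chromosome 5 (122506789 to 122506889), with 13 and 3. Gm22661 overlaps Zbed3 on the same strand. Gm15792, on chromosome 5 (110331206 to 110333203), is antisense to Pole, which encodes a DNA polymerase subunit, and their exons overlap, so without strand its reads cannot be told apart from those of Pole. It had 6.40 ± 0.11 FPKM in control and 4.77 ± 0.08 with overexpression (SD, n = 3; limma adjusted p = 0.510). Gm5453, a processed pseudogene on chromosome 13 (98904224 to 98904670) that can share reads with its parent gene, had 0.55 ± 0.12 and 1.61 ± 0.17 FPKM (SD, n = 3; limma adjusted p = 0.510). Of the 22 genes with an absolute log2 fold change of at least 1, 21 were small RNA genes. The exception, Clec3b, which encodes tetranectin, had 17.5, 19.4 and 5.06 FPKM in control replicates 1, 2 and 3 and 2.21, 3.76 and 6.06 FPKM with overexpression (limma adjusted p = 0.842).

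**Figure D2:**
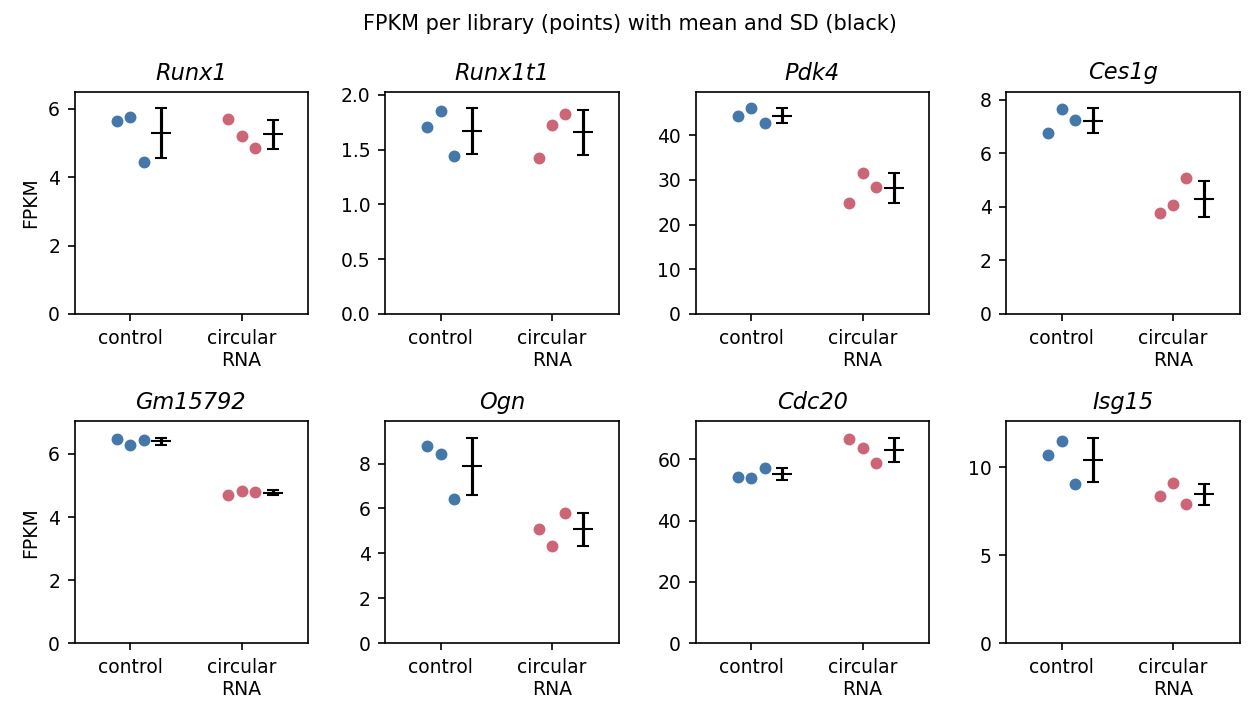
FPKM of 8 genes in the 3 control (blue) and 3 circular RNA overexpression (red) libraries, on linear axes from 0. Points are libraries and the black marks give the mean and SD of each group; Pdk4 lies at 42.8 to 46.0 FPKM in control and 24.8 to 31.5 with overexpression, and none of the 8 genes passed at an adjusted p of 0.05 (limma).

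Gene lists written before the data were examined were tested as groups. Of 34 lists, 33 had a tested member and 13 shifted against the remaining genes by camera with a preset correlation of 0.01, 7 towards higher and 6 towards lower values with overexpression. No list passed with the correlation between genes estimated from the libraries (smallest adjusted p = 0.709) or by fry (smallest adjusted p = 0.744). In none of the lists did a gene pass, either over all genes tested or adjusted over the list alone. Members named below are among the 2 with the smallest p of their list, chosen after the values were seen. They need not be typical of it. Ogn had a log2 fold change of -0.55 beside a list median of -0.11, whereas mt-Cytb at 0.25 lay near its list median of 0.28. The mean of a list separated the 3 libraries of one group from the 3 of the other in 2 lists. Chance gives 3.3 for independent libraries, and more if control replicates 1 and 2 act as 1 library. The smallest exact two-sided permutation p that 3 against 3 libraries allow is 0.1. With control replicates 1 and 2 averaged to 1 library, 4 of the 13 lists no longer passed camera, namely MYC and ribosome biogenesis (adjusted p = 0.067), matrix metalloproteinases (0.191), immediate early genes (0.232) and p53 targets (0.277). With array weights added, collagens and extracellular matrix (0.346), interferon-stimulated genes (0.130) and Notch and Hedgehog targets (0.130) were lost as well.

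Energy metabolism lists had small shifts towards higher values. All 29 tested nuclear-encoded genes of oxidative phosphorylation had estimates above 0, with a median log2 fold change of 0.13 (camera adjusted p = 2.31e-08; adjusted p = 0.709 with an estimated correlation). The groups overlapped on the mean of this list. Control replicates 1, 2 and 3 stood at -0.10, -0.09 and -0.002, and overexpression replicates 1, 2 and 3 at 0.14, 0.06 and -0.009. Cox4i1, a subunit of cytochrome c oxidase, had 147 ± 7.70 FPKM in control and 169 ± 3.78 with overexpression, and Atp5o, a subunit of ATP synthase, had 38.1 ± 0.65 and 43.6 ± 2.45 (SD, n = 3). All 14 tested mitochondrially encoded genes had estimates above 0, with a median of 0.28 (camera adjusted p = 5.09e-06; adjusted p = 0.709 with an estimated correlation). Among them mt-Cytb, which encodes cytochrome b, had 1733 ± 76.2 and 2066 ± 195 FPKM and mt-Nd3, a subunit of complex I, had 10.96 ± 1.69 and 13.5 ± 1.12 (SD, n = 3). Mitochondrial genes took 1.87%, 1.86% and 2.38% of the reads of control replicates 1, 2 and 3, and 2.01%, 2.57% and 2.43% with overexpression. On the list mean, control replicate 3 (0.15) lay above control replicates 1 and 2 (-0.29 and -0.27) and also above overexpression replicate 1 (-0.07), while overexpression replicates 2 and 3 stood at 0.31 and 0.17.

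Proliferation and translation lists also shifted towards higher values. All 35 tested genes of G2/M and mitosis had estimates above 0, with a median of 0.09 (camera adjusted p = 8.98e-07; adjusted p = 0.709 with an estimated correlation). Cdc20, an activator of the anaphase-promoting complex, had 55.1 ± 1.86 FPKM in control and 63.1 ± 3.98 with overexpression, and Cenpe, a kinetochore motor protein, had 15.0 ± 0.46 and 16.5 ± 0.34 (SD, n = 3). In this list the control means (-0.05, -0.04 and -0.05) all lay below the overexpression means (0.11, 0.05 and -0.02). Of 34 tested G1/S and DNA replication genes 31 had estimates above 0, with a median of 0.09 (camera adjusted p = 6.29e-05; adjusted p = 0.709 with an estimated correlation). Here the groups overlapped, with control means of -0.09, -0.07 and 0.01 and overexpression means of 0.15, 0.05 and -0.06. Pola1, a DNA polymerase subunit, had 7.29 ± 0.16 and 8.18 ± 0.11 FPKM (SD, n = 3). Without overexpression replicate 1 the G1/S median was 0.04 and the list no longer passed (camera adjusted p = 0.069).

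Of 46 tested cytosolic ribosomal protein genes 45 had estimates above 0, with a median of 0.10 (camera adjusted p = 1.20e-06; adjusted p = 0.709 with an estimated correlation). The list means overlapped, at -0.10, -0.09 and 0.04 in control replicates 1, 2 and 3 and -0.03, 0.07 and 0.11 with overexpression. Rplp2 had 457 ± 18.3 FPKM in control and 514 ± 18.2 with overexpression and Rps25 had 1495 ± 17.1 and 1649 ± 62.1 (SD, n = 3), and reads of such genes can be shared with their many pseudogenes. After quantile normalization the median of this list was 0.01 (camera adjusted p = 0.796). Of 25 MYC target and ribosome biogenesis genes 23 had estimates above 0, with a median of 0.17 (camera adjusted p = 0.0011; adjusted p = 0.798 with an estimated correlation). Pes1, a factor of large ribosomal subunit assembly, had 39.6 ± 5.31 and 47.1 ± 1.69 FPKM and Utp20, a factor of small subunit processing, had 12.9 ± 2.14 and 15.1 ± 1.12 (SD, n = 3). For the MYC list the mean of control replicate 3 (0.18) lay above those of overexpression replicates 2 and 3 (0.004 and -0.07) and below that of overexpression replicate 1 (0.29), with control replicates 1 and 2 at -0.20 and -0.19. The MYC median was 0.03 without overexpression replicate 1 (camera adjusted p = 0.522), 0.10 without control replicate 1 (0.093) and 0.09 without control replicate 2 (0.070). Of 21 tested p53 target genes 17 had estimates above 0, with a median of 0.10 (camera adjusted p = 0.041; adjusted p = 0.795 with an estimated correlation). On the list mean, control replicate 3 (0.15) lay above all overexpression libraries (0.07, -0.002 and 0.08), while control replicates 1 and 2 stood at -0.14 and -0.15. Fas, a death receptor, had 6.34 ± 0.80 and 7.57 ± 0.79 FPKM and Ei24 had 21.7 ± 2.08 and 24.7 ± 2.30 (SD, n = 3). The p53 call was lost without control replicate 1, without control replicate 2, without overexpression replicate 1 and without overexpression replicate 3, with medians of 0.05, 0.08, 0.10 and 0.07, and also at a filter of 5 FPKM (camera adjusted p = 0.128), without a filter (0.054) and after quantile normalization (0.16).

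**Figure D3:**
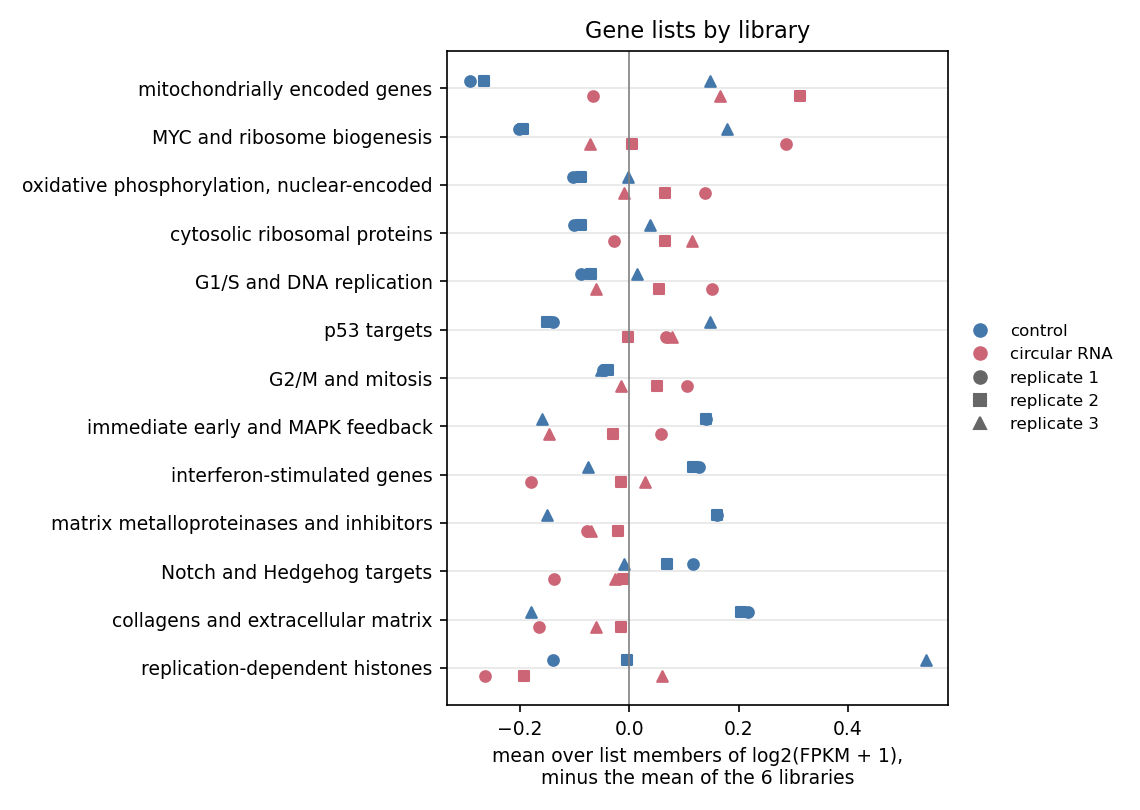
Mean of log2(FPKM + 1) over the members of each of the 13 gene lists that passed camera with a preset correlation, per library, after subtracting the mean of the 6 libraries. Points are libraries, coloured by group and shaped by replicate; the groups separate in G2/M and mitosis and in Notch and Hedgehog targets, and control replicate 3 lies away from control replicates 1 and 2 in most other lists, for example at 0.54 against -0.14 and -0.01 in histones. No list passed with an estimated correlation (smallest adjusted p = 0.709).

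Matrix lists shifted towards lower values. Of 29 tested collagen and extracellular matrix genes 21 had estimates below 0, with a median log2 fold change of -0.11 (camera adjusted p = 0.00072; adjusted p = 0.709 with an estimated correlation). The 2 members with the smallest p were Ogn, the small proteoglycan osteoglycin, and Fbln2, fibulin 2. Ogn had 7.88 ± 1.27 FPKM in control and 5.07 ± 0.74 with overexpression, and Fbln2 had 66.6 ± 4.22 and 56.0 ± 3.28 (SD, n = 3). The list mean of control replicate 3 (-0.18) lay below all overexpression libraries (-0.17, -0.01 and -0.06), while control replicates 1 and 2 stood at 0.22 and 0.20. Of 15 tested matrix metalloproteinase and inhibitor genes 11 had estimates below 0, with a median of -0.15 (camera adjusted p = 0.031; adjusted p = 0.709 with an estimated correlation). The list mean of control replicate 3 (-0.15) again lay below all overexpression libraries (-0.08, -0.02 and -0.07), while control replicates 1 and 2 both stood at 0.16. Mmp11 had 9.62 ± 0.99 and 8.0 ± 0.32 FPKM and the aggrecanase Adamts5 had 18.4 ± 1.85 and 15.4 ± 1.22 (SD, n = 3). This call was lost without control replicate 1 or 2 and without overexpression replicate 1 or 3, with medians of -0.06, -0.12, -0.14 and -0.17, and after rescaling to total reads (median -0.18, camera adjusted p = 0.065) or to the upper quartile (-0.17, 0.052) and without a filter (-0.11, 0.143).

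Interferon-stimulated genes shifted towards lower values, with estimates below 0 in 18 of 22 and a median of -0.12 (camera adjusted p = 0.0013; adjusted p = 0.709 with an estimated correlation). The list mean of control replicate 3 (-0.08) lay below overexpression replicates 2 and 3 (-0.02 and 0.03) and above overexpression replicate 1 (-0.18). Control replicates 1 and 2 stood at 0.13 and 0.12. Isg15, a ubiquitin-like protein, had 10.4 ± 1.26 FPKM in control and 8.46 ± 0.59 with overexpression, and Ifi27 had 39.4 ± 1.15 and 34.3 ± 2.17 (SD, n = 3). Without overexpression replicate 1 the median was -0.06 and the list did not pass (camera adjusted p = 0.069). All 8 tested Notch and Hedgehog targets had estimates below 0, with a median of -0.10 (camera adjusted p = 0.0034; adjusted p = 0.709 with an estimated correlation), and this call too was lost without overexpression replicate 1 (median -0.05, camera adjusted p = 0.065). The Notch ligand gene Jag1 had 10.6 ± 0.43 and 9.50 ± 0.36 FPKM and Hes1, a transcriptional repressor induced by Notch, had 2.31 ± 0.41 and 1.75 ± 0.27 (SD, n = 3).

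Of 18 tested replication-dependent histone genes 14 had estimates below 0, with a median of -0.20 (camera adjusted p = 0.0011; adjusted p = 0.709 with an estimated correlation), in contrast to the cell cycle lists. Hist1h1c had 21.8 ± 3.48 and 12.8 ± 5.01 FPKM and Hist1h3h had 1.69 ± 0.64 and 0.84 ± 0.18 (SD, n = 3); reads of histone genes can be split between near-identical copies. Control replicate 3 had the highest list mean (0.54), beside -0.14 and -0.005 in control replicates 1 and 2 and -0.27, -0.19 and 0.06 with overexpression, and without it the median was -0.01 (camera adjusted p = 0.364). The histone list also did not pass with array weights (camera adjusted p = 0.072) or quality weights (0.593). Immediate early and MAPK feedback genes had estimates below 0 in 21 of 31, with a median of -0.06 (camera adjusted p = 0.043; adjusted p = 0.709 with an estimated correlation). Here too control replicate 3 (-0.16) lay below all overexpression libraries (0.06, -0.03 and -0.15), with control replicates 1 and 2 both at 0.14. Dusp1, a MAP kinase phosphatase, had 69.7 ± 10.8 and 58.5 ± 5.94 FPKM and the transcription factor Klf2 had 52.9 ± 9.45 and 43.9 ± 4.26 (SD, n = 3). Unlike the list mean, Klf2 was highest in control replicate 3, at 63.8 FPKM beside 48.2 and 46.8 in control replicates 1 and 2. Its log2 fold change was -0.25, and -0.11 without control replicate 3. The immediate early call was lost without control replicate 1, control replicate 2 or overexpression replicate 3, with medians of -0.04, -0.03 and -0.03, and after rescaling to total reads (-0.09, camera adjusted p = 0.071) or to the upper quartile (-0.08, 0.054), GC correction (-0.06, 0.070) and removal of the filter (-0.06, 0.086).

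The remaining 20 lists with a tested member did not pass camera. Camera adjusted p was 0.086 for heat shock genes, 0.115 for growth factors and receptors, 0.126 for both cholesterol biosynthesis and TGF-beta targets, 0.337 for both NF-kB and inflammatory genes and glycolysis and hypoxia, 0.358 for the unfolded protein response, 0.399 for fatty acid synthesis and adipocyte genes and 0.630 for circular RNA handling factors. It was 0.675 for the parent genes and core-binding factors, Wnt targets and contractile and SRF targets, 0.726 for YAP/TAZ targets, 0.779 for NRF2 antioxidant and lysosome genes, 0.879 for apoptosis regulators and 0.935 for ATF4 and amino acid stress. Cholesterol biosynthesis genes passed in opposite directions in other settings, with a median of -0.11 without control replicate 3 (camera adjusted p = 0.018), 0.26 without control replicate 1 (0.00022), 0.27 without control replicate 2 (4.11e-05) and 0.26 with control replicates 1 and 2 averaged (8.96e-05). They also passed without overexpression replicate 1 (0.23, camera adjusted p = 0.011), in limma-voom (0.16, 0.026), after rescaling to total reads (0.11, 0.039) and with averaged controls and array weights (0.43, 2.04e-09). ATF4 and amino acid stress genes likewise passed with both signs, with a median of 0.26 without control replicate 3 (camera adjusted p = 8.69e-10), 0.21 with array weights (0.00051), -0.06 without control replicate 1 (0.035) and -0.05 with averaged controls (0.047). Without control replicate 3, NF-kB (-0.15, camera adjusted p = 0.0010), growth factor (-0.20, 0.0014), heat shock (0.11, 0.025) and NRF2 (0.16, 0.04997) lists passed as well. NRF2 genes passed with the other sign with averaged controls and array weights (-0.11, camera adjusted p = 0.037). Without overexpression replicate 1 the NF-kB (-0.12, camera adjusted p = 0.0048) and contractile (-0.02, 0.038) lists passed, without overexpression replicate 2 the growth factor list (-0.15, 0.025), without overexpression replicate 3 the unfolded protein response (0.19, 0.015) and without control replicate 1 the leukocyte markers (-0.13, 0.025). The median, the mean and the test differed in sign for contractile and SRF targets, YAP/TAZ targets, NRF2 antioxidant genes and apoptosis regulators. Markers of other cell types were mostly below the expression filter, with 4 leukocyte, 2 epithelial, 2 muscle or neural and 0 endothelial markers tested, and the first 3 of these lists had camera adjusted p of 0.141, 0.779 and 0.675.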

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

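The settings with library weights, averaged controls, recovered reads, rescaling, quantile normalization, protein-coding genes only and length were chosen after seeing the data. No gene passed in the limma fit as planned (632 at an unadjusted p below 0.05), and 0 passed under the pseudocounts, filters, GC and length corrections, rescalings, quantile normalization, limma-voom, protein-coding genes only, the 1.5-fold test and averaged controls, with or without array weights. Quality weights gave 729 of 14473 tested genes (89 with an absolute log2 fold change of at least 1) and array weights 2241 of 12222 (44). Leaving out a library gave 0 to 2 genes, 2 without control replicate 3 and 1 without overexpression replicate 1, and 0 to 1 of at least 1 in size. Genes at an unadjusted p below 0.05 numbered 1870 without control replicate 3, 258 and 279 without control replicates 1 and 2, 383 and 997 without overexpression replicates 2 and 3, 240 with averaged controls (481 with array weights added), 3746 and 4589 with quality and array weights, 1160 without a filter and 413 with the filter at 5 FPKM; the last pair test more and fewer genes. The cause of the other differences was not tested.

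Replicate numbers did not pair the libraries: correlations of same-numbered deviations were -0.10, 0.08 and 0.003, and not every library correlated best with its own number. With the replicate block 0 genes and 14 lists passed, the 13 and cholesterol biosynthesis (median 0.13, camera adjusted p = 0.022), and 444 genes at an unadjusted p below 0.05.

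Of the 13 lists, 0 passed with an estimated correlation and 0 by fry. G2/M, nuclear-encoded oxidative phosphorylation and mitochondrially encoded genes passed camera with the preset correlation in all 23 other settings. Of the 13, 9 were kept with averaged controls and 6 with averaged controls and array weights, 12 with array weights, 12 with quality weights and 10 without a filter; with a library left out 7 (without overexpression replicate 1) to 13 (without overexpression replicate 2) were kept. Without control replicate 3, 18 lists passed, 6 of them not among the 13, which included NRF2 genes (camera adjusted p = 0.04997).

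Of 936 comparisons of 42 genes, 12 taken by the rule set beforehand and 30 chosen after the values were seen, with another setting, 15 changed direction, all of Runx1 (-0.0041) and Runx1t1 (-0.0061), and 57 passed, 54 of them with library weights. Runx1 and Runx1t1 stood at 0.045 and 0.025 with averaged controls, 0.032 and 0.060 with averaged controls and array weights, 0.015 and 0.0056 without the length trend, and 0.014 and 0.044 after quantile normalization. With a library left out they ran from -0.10 to 0.052 and -0.068 to 0.058. The collagen median turned to 0.0096 with averaged controls and array weights. The other reversals were of lists that did not pass in the limma fit as planned. With averaged controls the medians were 0.025 (parent genes), -0.051 (ATF4), -0.032 (NRF2) and 0.022 (lysosome), and with array weights added 0.033, -0.078, -0.11 and 0.067, with -0.025 (contractile), -0.033 (YAP/TAZ), 0.033 (apoptosis), -0.018 (circular RNA handling), 0.038 (growth factors) and -0.15 (muscle and neural). With array weights alone contractile, YAP/TAZ and apoptosis stood at -0.069, -0.064 and 0.028, and with quality weights at -0.16, -0.064 and 0.025, with -0.0032 for circular RNA handling. Parent genes stood at 0.0056 without the length trend and 0.014 after quantile normalization. YAP/TAZ was -0.0051 after quantile normalization, -0.025 after rescaling to total reads and -0.017 to the upper quartile, NRF2 -0.026 after quantile normalization, and circular RNA handling -0.00064 after rescaling to total reads. Apoptosis was 0.0019 at the filter of 5 FPKM and 0.0081 after GC correction with or without the block. Contractile and epithelial markers were -0.035 and -0.021 without a filter and -0.017 and -0.022 in limma-voom. With a library left out the medians ran from -0.068 to 0.033 (parent genes), -0.056 to 0.26 (ATF4), -0.076 to 0.16 (NRF2), -0.031 to 0.029 (YAP/TAZ), -0.023 to 0.030 (apoptosis), -0.11 to 0.27 (cholesterol), -0.021 to 0.058 (circular RNA handling), -0.021 to 0.057 (contractile), -0.082 to 0.030 (lysosome), -0.040 to 0.28 (muscle and neural) and -0.0041 to 0.19 (unfolded protein response).

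The fits by DESeq2 and by edgeR with other normalizations, and the CPM filter, were not run. The files hold FPKM, and although reads were recovered from them, these were tested with limma-voom only. Depth limits the small RNA genes named, which rest on 10 to 56 reads over the 6 libraries.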

Other observations

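All tests below were chosen after the results they bear on were seen, except the GC correction, the pseudocounts, the filters, the replicate block, the leaving out of each library and the estimated correlation, which were planned. Fn1, which encodes fibronectin, stood at 541, 537 and 319 FPKM in control replicates 1, 2 and 3 and at 243, 345 and 343 FPKM with overexpression. Cholesterol biosynthesis genes had list means of 0.17, 0.21 and -0.58 in control replicates 1, 2 and 3 and of -0.13, 0.30 and 0.04 with overexpression, and ATF4 and amino acid stress genes had -0.28, -0.25 and 0.48 against 0.03, 0.003 and 0.009. In both lists the spread between the controls exceeded the difference between the groups.

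The first pattern is the shift of 13 gene lists. A gene length trend does not account for it alone, since all 13 passed camera in the same direction after the trend was removed, nor does GC content, since 12 did after that correction. Whether variation between libraries shared by the genes of a list accounts for it stays open. With a correlation estimated from the libraries 0 lists passed, but that test has few residual degrees of freedom at 3 against 3 libraries. Even for oxidative phosphorylation, with all 29 estimates above 0, its unadjusted p was 0.086 (camera). The other splits of the 6 libraries into 3 and 3 gave up to 21 lists. With the real one included, 4 of the 10 splits gave 13 or more. The real grouping thus did not stand out by its number of lists, though 10 splits could not have given a share under 0.05. An effect of the circular RNA on these lists stays open and untested beyond this comparison.

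The second pattern is the number of genes called once libraries are weighted, 729 with quality weights and 2241 with array weights, beside a chi-square per gene of 1.46 between control replicates 1 and 2, whose 95% interval above 1 argues against a repeat deposit with counting error alone but leaves 2 libraries of one RNA or culture open. With quality weights the 6 splits that part the pair gave 0 genes. The 4 that keep it together, the real one included, gave 668 to 1086. This does not single out the weights, since parting the pair also went with fewer genes in the unweighted limma fit. At an unadjusted p below 0.05 that fit held 126 to 305 genes in the parted splits and 632 to 2100 in the others. The real split held 632, the fewest of those that keep the pair together. Whether the weight on the pair produces the calls stays open. With array weights the weight on the pair alone does not account for them, since the 3 other splits that keep it together, with mean weights on it of 2.65 to 2.80 against 2.36, gave 272, 2 and 0 genes; the highest weight lay on control replicate 2 in those splits (2.88 to 3.23) and on overexpression replicate 2 in the real one (4.64). A part of the pair and of overexpression replicate 2 in these calls stays open, since averaging the pair left 0 genes, in a fit with fewer residual degrees of freedom, equal weights on both controls (0.683) and 5.82 on overexpression replicate 2. With quality weights 2 of the 10 splits, the real one included, gave at least the real count (highest other 1086), so the real one did not have the most. With array weights only 1, the real one, did so (highest other 272), and 10 splits are too few for a share under 0.05.

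The 0 genes called without weights cannot be set against other splits in this way, since all 10 give at least 0; the highest other split gave 1.

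The third pattern is the lower Pdk4 in the overexpression libraries, which did not pass after adjustment. Scaling or the pseudocount does not account for it alone, since the log2 fold change nearest to 0 over 6 such settings, limma-voom included, was -0.58, beside -0.64 as reported. Its rank by p among protein-coding genes moved from 1 to 29 without control replicate 3, 5 without overexpression replicate 3, 2 without overexpression replicate 1, and 3 with array weights with or without averaged controls, and its adjusted p ran from 0.0023 to 0.9998 over all settings. Pdk4 was picked for its small p among 12222 genes, so selection stays open. An effect of the circular RNA stays open too. A measurement in separate cultures could test whether lower Pdk4 recurs. Against wild type controls it could not tell the circular RNA from the overexpression procedure.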
